A study of Mus musculus with 8 samples.

How the data were processed

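RNA of mouse 3T3-L1 cells was measured on 8 Agilent one-colour arrays, 1 for each of 2 cell lines at each of 4 days. Although the series description names another array maker, the deposited files are Agilent scanner output. Per the labels, RNA was taken with TRIzol, 1 µg of it was labelled with Cy3 by the Quick Amp kit, and cells were grown in 10% newborn calf serum before induction. Per the file headers, the authors read each array in 1 colour with Agilent Feature Extraction 11.0.1.1, and the deposited files give each spot a processed intensity next to its median, background and background-subtracted signals. The processed intensities had a different 75th percentile on each array, so they were not on a common scale between arrays. The authors also deposited a value table of the same arrays on a log2 scale. Its columns shared their quantiles and had medians of 6.39, and each correlated best with its own array (r from 0.994 to 1.00 across probes), with no centring per gene and in the same direction. How the authors reached those values is not given in the sources used here, so the table served as an alternative.

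Each array held 44397 spots, of which 1377 were controls and were left out. Repeat spots of a probe were averaged, giving 39429 distinct probes, and 46 probes were left out for an outlier flag on an array. Through their RefSeq accessions, compared without version numbers, 27234 probes received a symbol from a table of the GRCm38.p6 assembly and 12195 did not. The table served for names only, and no coordinate is given, because the file headers name the older build mm9. Values were the log2 processed intensity minus the array's own 75th percentile, so that 0 is the level of that percentile. A probe was kept if it was well above background on at least 2 of the 8 arrays. Of several probes for a gene, the 1 with the highest mean was kept (4400 genes had more than 1). This left 26461 genes and unnamed transcripts, 17548 of them named and 8913 unnamed.

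Tests were run with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package, version 1.17.8, and p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. The model for sh8 against WT and for the day comparisons held day as a factor with 4 levels and line as a covariate, over all 8 arrays, which leaves 3 residual degrees of freedom. A second model added the interaction of line with the period after induction (days +2 and +4) and leaves 2. A pair of arrays from 1 day has no test, so the single-day comparisons list genes that differed by at least 1 on the log2 scale and were well above background on at least 1 of the 2 arrays. A gene that was well above background on no array of a group has only a bound there. Its change is written "at least N-fold", from the bright group's mean against a dim mean that uses, on each array, the higher of the gene's own value and the lowest value among probes well above background.

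Gene lists were tested by camera with a preset correlation between genes of 0.01, which compares a list with all other genes, and again with the correlation estimated from the data. The fry test asks whether a list's genes move 1 way on balance. All list p-values are adjusted over the 29 lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone. On single days a list's median is placed as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins. Random lists are not matched on the correlation between genes, so such a percentile is a place and no p-value. These 29 lists, the tests and the rule for naming genes were fixed before the data were examined. A further 10 lists of tissue markers (lung epithelium, red blood cells, lung leukocytes, liver, kidney, brain, testis, pancreas, skin and forestomach, intestine) were written after lung genes had been seen on some arrays. The comparison of day +4 with day +2 was also added after the data were seen.

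Genes were named by a fixed rule. For sh8 against WT and each day comparison these were the 10 most positive and 10 most negative changes among named genes past the threshold that moved the same way in every pair. Where fewer than 5 passed in a direction, the 5 with the lowest unadjusted p are given and said not to pass. The change after induction followed this rule without the pair condition, with up to 10 each way. For single days the rule took the 5 largest differences each way among genes well above background on both arrays. From each list described it took up to 4 members past the threshold with the lowest p, or up to 2 if none passed. Pparg, Cebpa, Cebpb, Cebpd, Fabp4, Adipoq, Cdkn1a and Dnmt1 were always given. The lung genes and the few other genes outside this rule were chosen after their values were seen. 1 gene that the rule names is not reported here.

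Simulated data with 200 changed genes among the 26461 tested the procedure. For sh8 against WT, 28.4% of the genes changed 2-fold, 68.7% of those changed 4-fold and 86.4% of those changed 8-fold were called, with 12 false calls. For day +2 against day 0 the shares were 11.9%, 61.2% and 77.3% (3 false calls), for day +4 against day 0 they were 7.46%, 55.2% and 75.8% (5), for day 0 against day -2 4.48%, 52.2% and 74.2% (0), and for day +4 against day +2 7.46%, 56.7% and 74.2% (5). For the change after induction 0% of the changed genes were called at each of these sizes, with 0 false calls, so a count of 0 there is no evidence against such changes. The simulated noise came from the model without the interaction, whose spread also holds any real change after induction, so these shares may be too low. The adjustment is also stricter when few genes change. For the change after induction 19.9% of genes in the data had an unadjusted p under 0.05, against 5.16% of the unchanged simulated genes. The shares called therefore do not carry over directly to the data. A cholesterol list moved by -1 on the log2 scale was called by camera with an adjusted p of 2.23e-38, and 0 of the other lists were. The simulated noise was drawn for each gene on its own, so it does not test lists whose genes vary together. In the data the estimated correlation between genes was 0.34 for cholesterol synthesis and 0.93 for S phase.

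Alternatives covered normexp background correction (offset 50, on the median spot signal since the mean signal was not used here), quantile scaling, scaling by the median of probes above background on all arrays, and the authors' value table. They also covered no filter and a filter on all 8 arrays, each probe on its own or the mean over probes, a trended or robust eBayes, a 1.5-fold minimum, models without the day or line term, and leaving out each day or array. Added after the data were seen were each slide alone and bright genes alone (mean above the 75th percentile).

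Per the file headers, the arrays of days -2 and 0 lay on 1 slide and those of days +2 and +4 on another, with WT at positions 1 and 2 and sh8 at positions 3 and 4 of each slide. Slide therefore cannot be told apart from the period before or after induction, nor position from line. Slide could replace day as a block for sh8 against WT, but it could not be added to the comparisons of day +2 or +4 with day 0. The shared days pair the arrays of the lines by design. A probe for slincRAD was not named by the tables used here, and its level was not analysed here.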

Results

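3T3-L1 cells are mouse preadipocytes that turn into fat cells when a confluent culture receives a hormone mix. Gene expression was measured in unmodified cells (WT) and in cells that stably carry shRNA-8, a short hairpin RNA against the long noncoding RNA slincRAD (sh8). Cells were sampled at days -2, 0, +2 and +4. Day 0 is confluence, after which the cells were induced with 0.5 mM isobutylmethylxanthine, 1 µM dexamethasone and 167 nM insulin. Each line and day gave 1 array, so 8 arrays were compared and no line and day has a replicate. The 75th percentile of intensity ran from 761 (sh8, day +4) to 1242 (WT, day -2), 64.9% to 81.7% of probes were well above background, and 0 spots were saturated. The number of arrays limits the precision. Nothing in the labels says that the arrays are separate cultures, and with 1 array per line and day the p-values measure how much a difference between the lines varied from day to day, or a difference between days from line to line, which may be partly technical. The level of slincRAD was not analysed here and no line with a control shRNA was among the samples, so the labels of the lines were not checked against the target. The arrays of days -2 and 0 lay on a first slide and those of days +2 and +4 on a second.

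The main question was how sh8 cells differed from WT cells over the course of differentiation. The fat cell genes Pparg and Fabp4 were lower in sh8, and so were the lists of cholesterol synthesis, DNA replication and interferon response genes by camera with its preset correlation. With an estimated correlation these 3 lists had an adjusted p = 0.772, 0.796 and 0.796, and fry gave 0.0317, 0.193 and 0.107. Pparg, the nuclear receptor that drives fat cell formation, was 3.01-fold lower (log2 change -1.59 ± 0.17 SE, adjusted p = 0.0116), by -1.15, -1.41, -1.95 and -1.84 at days -2, 0, +2 and +4. Fabp4, the fatty acid carrier of fat cells, was 2.90-fold lower (-1.53 ± 0.13, adjusted p = 0.0101). Cdkn1a, which encodes the cell cycle inhibitor p21, was 1.46-fold higher (0.55 ± 0.12, adjusted p = 0.0331), although its dimmer second probe differed by only 0.11. Adipoq (-1.23, adjusted p = 0.18, well above background on 2 arrays of each line), Cebpa (0.37, 0.13), Cebpb (-0.073, 0.682), Cebpd (-0.0015, 0.996) and Dnmt1, the maintenance DNA methyltransferase (0.025, 0.948), did not pass.

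**Figure D1:**
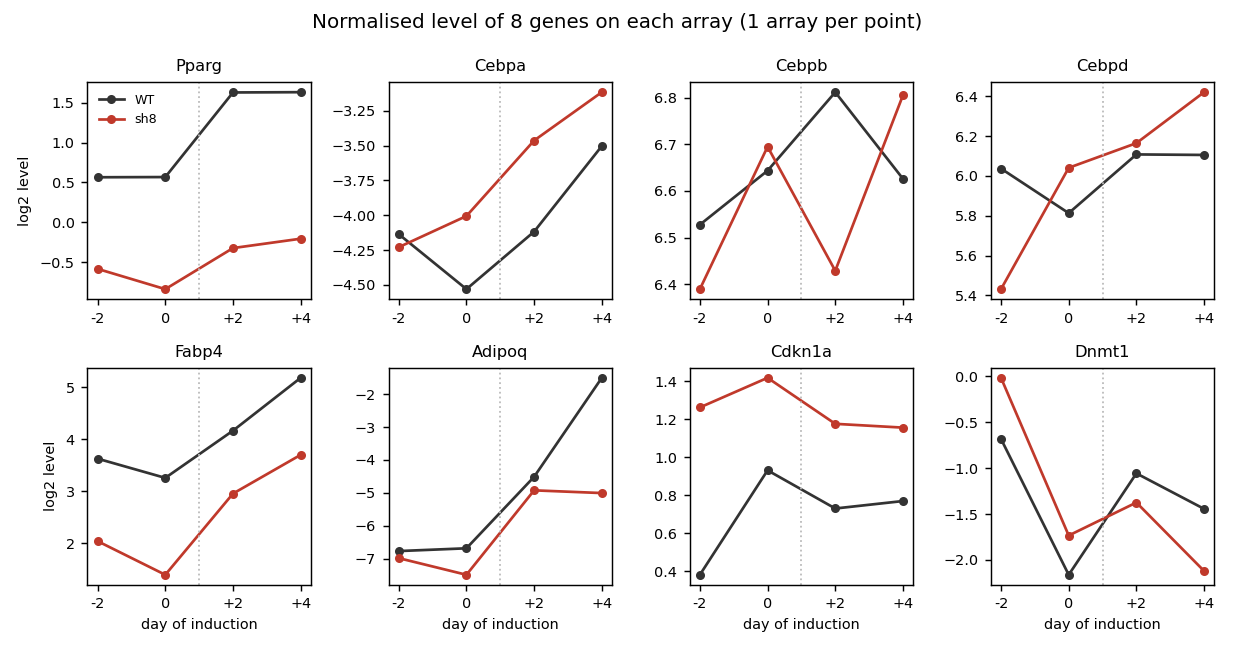
Normalised log2 level of the 8 genes chosen in advance on each array, by day, with WT in black and sh8 in red, 1 array per point and the dotted line between the slides. Pparg lay between 0.57 and 1.63 in WT and between -0.84 and -0.21 in sh8, and Adipoq in sh8 was at -5.01 at day +4, below WT.

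In total 7158 of 26461 genes and transcripts (27.1%) differed between the lines, 4436 higher and 2722 lower in sh8, and 1783 of them differed at least 2-fold. Of the named genes 2803 were higher and 2182 lower. With quantile scaling 2641 were higher and 2572 lower, and with the authors' values 2729 and 2623. The median of all genes lay 0.13 above 0, and the list tests below are relative to the other genes. With the slide as a block in place of day 5023 genes passed, on the second slide alone 5111 did, and on the first slide alone 0 did by limma, with 8387 at an unadjusted p under 0.05. Leaving out day +2 or day +4 left 0 genes (9445 and 8653 unadjusted), leaving out day 0 left 81 and leaving out day -2 left 4212. The call of each gene named in this comparison was therefore lost without day +2 and without day +4.

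Among mature fat cell markers, 5 of 22 measured genes fell and 1 rose (5 and 2 adjusted over the list alone). Agt, the angiotensin precursor (-1.86), Lpl, the lipase that frees fatty acids from lipoproteins (-1.39), and the lipid droplet protein Plin4 (-2.16) fell with Fabp4. The list as a whole did not pass (adjusted p = 0.064, and 0.796 with an estimated correlation). Among adipogenic transcription factors 5 of 19 fell and 1 rose (5 and 2 over the list alone), with Ebf1 at -0.81, Zfp423 at -0.72 (-0.30 and -0.51 for its other probes) and the oxysterol receptor Nr1h3 at -0.47 (-0.11 for its second probe) beside Pparg, and the list did not pass (adjusted p = 0.192). Of 21 preadipocyte genes 6 fell and 4 rose (7 and 4 over the list alone), and camera gave no call (adjusted p = 0.215, and 0.772 with an estimated correlation) where fry did (0.0122). The secreted Wnt modulator Sfrp2 fell by 4.21 and Wnt6 by 2.08, while the surface markers Thy1 (1.21) and Ly6a (1.45) rose. The brown fat coactivators Ppargc1b (-1.69) and Ppargc1a (-1.71) fell, whereas Prdm16 (0.35, adjusted p = 0.0405, well above background on 2 sh8 arrays and 1 WT array) rose, but was at -0.0050 with quantile scaling and at -0.065 in the authors' values, neither of which passed. Of these 11 brown fat genes 1 rose and 2 fell, over all genes and also adjusted over the list alone. The list median was 0.18 and its mean 0.042, while camera, which set it against other genes, pointed down and did not pass (adjusted p = 0.9).

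Cholesterol synthesis genes were lower as a group. Of 22 measured genes 15 fell (16 adjusted over the list alone), with a median log2 change of -0.95 (camera adjusted p = 4.68e-10, fry adjusted p = 0.0317). The camera call was lost at an adjusted p = 0.772 with an estimated correlation. Lanosterol synthase Lss fell by 1.42, the sterol sensor Insig1 by 1.28, Msmo1 by 1.55 and Hsd17b7 by 0.72. The median difference was -0.59, -1.13, -0.58 and -1.22 at days -2, 0, +2 and +4, lower than at least 99.95% of matched random lists on each day. Those random lists were not matched on the correlation between cholesterol genes (0.34), so this share is no p-value. On the first slide alone the list median was -0.88 (camera adjusted p = 4.28e-08).

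Genes of DNA replication licensing and S phase had a median change of -1.04 (adjusted p = 2.78e-08, but an adjusted p = 0.796 with an estimated correlation). Over all genes 9 of 36 fell, and over the list alone 14 fell and 1 rose. The replication clamp Pcna (-0.96), the chromatin assembly subunit Chaf1b (-1.59), the transcription factor E2f1 (-1.07) and the licensing factor Cdt1 (-1.41) were the 4 with the lowest p. Genes of G2 and mitosis had a median of -0.90 (adjusted p = 7.59e-05, and an adjusted p = 0.796 with an estimated correlation), yet 0 of 33 passed by limma over all genes or over the list alone. At an unadjusted p under 0.05, 8 of these were lower and 1 higher, and Cdc25c (-1.01, adjusted p = 0.0514, well above background on 3 arrays of each line) and Ndc80 (-0.83, 0.0838) came closest. On the first slide alone the S phase list kept a median of -0.36 (adjusted p = 0.00267), and that of G2 and mitosis was -0.11 (0.492). Without day +4 the medians were -0.69 (adjusted p = 6.39e-07) and -0.39 (adjusted p = 0.00751).

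Interferon response genes were lower in sh8 with a median of -0.75 (adjusted p = 1.12e-07, and an adjusted p = 0.796 with an estimated correlation). Of 34 genes 13 fell (14 over the list alone), among them the GTPases Ifi47 (-1.65) and Irgm1 (-1.03), Ifit2 (-0.71) and the viral tether Bst2 (-1.38). The first slide alone gave -0.79 (adjusted p = 9.28e-08). The list median was -0.45 (adjusted p = 1.77e-05) without day -2, and at day +4 it was -0.19. Respiratory chain genes had a median of -0.18 (adjusted p = 5.60e-05, 0.772 with an estimated correlation), with 6 of 32 lower (3 over the list alone), such as Ndufa4 (-0.55), Atp5c1 (-0.48, and -0.24 for its second probe), Ndufa9 (-0.78) and Cox4i1 (-0.40), and the first slide alone gave -0.14 (adjusted p = 0.0229). The list of fatty acid oxidation had an adjusted p = 0.0333 and an adjusted p = 0.772 with an estimated correlation. Its members went both ways, with 4 of 19 lower and 2 higher (7 and 3 over the list alone). Acaa2 (0.95) and the carnitine transferase Cpt1a (1.16, and 0.60 for its second probe) rose while Pex11a (-0.72) and Etfdh (-0.46) fell. This call was lost with quantile scaling (adjusted p = 0.353), without day +2 (0.0698), without day +4 (0.0966) and on the first slide alone (0.267).

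Macrophage and leukocyte markers were higher in sh8, with a median of 0.46 (camera adjusted p = 0.00755, 0.772 with an estimated correlation; fry adjusted p = 0.00947). Of 15 genes 7 rose (11 over the list alone), including Aif1 (0.73), Adgre1 (0.56), Lyz2 (0.87, well above background on 2 arrays of each line) and Itgam (0.46, and 0.17 and 0.25 for its other probes). Transcripts typical of lung epithelium, which appeared on the second slide, were also higher there in sh8, with list medians of -2.33 and -2.10 at days +2 and +4 against -2.84 and -2.51 in WT. On the first slide alone the macrophage list had a median of 0.37 (adjusted p = 0.0306), and with normexp one of 0.28 (adjusted p = 0.00995). Matrix and fibroblast genes moved in both directions, 9 of 31 up and 4 down (11 and 4 over the list alone), with fibrillin Fbn1 at 1.83 and Col5a1 at 0.58 but Lum at -2.54 (well above background on 3 sh8 arrays) and Postn at -2.38. Their median was 0.20 and their mean -0.0084, and camera gave no call (adjusted p = 0.797) where fry did (0.00947).

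By fitted difference, the 10 named genes lowest in sh8 included the small GTPases Rab12 (-6.80 ± 0.95) and Rab29 (-4.59 ± 0.37), Tpd52l1 (-5.62 ± 0.72), Mst1 (-5.03 ± 0.24), Renbp (-4.81 ± 0.51) and the acyl-CoA thioesterase Acot1 (-4.72 ± 0.42). The amino acid transporter Slc7a2 (-4.36 ± 0.27), the bombesin receptor family member Grpr (-4.35 ± 0.31), Sfrp2 and Ugt2b35 (-4.65 ± 1.00) completed this group, with adjusted p between 0.00737 for Mst1 and 0.0319 for Ugt2b35. All 10 were well above background on all 4 WT arrays. In sh8, Mst1, Slc7a2 and Grpr were well above background on 4 arrays, Acot1, Rab29 and Sfrp2 on 3, Rab12, Renbp and Ugt2b35 on 2 and Tpd52l1 on 1. The second probe of Rab29, well above background on all 8 arrays, differed by only -1.47, those of Mst1 and Renbp by -3.78 and -4.08, and the dim one of Ugt2b35 went the other way (0.78). By its chosen probe Ugt2b35 differed by only -0.95 at day -2 and by -6.85, -5.49 and -5.30 at days 0, +2 and +4. The 10 genes highest in sh8 by fitted difference included 6 known only by a bound, so they have no order among themselves. They were Jakmip2 (at least 19.2-fold, adjusted p = 0.00604) and 9 others, Spag17 (5.84 ± 0.93), Hrnr (5.18 ± 0.93), Mlip (5.03 ± 0.94), Igsf5 (4.54 ± 0.50), Krt4 (at least 15.6-fold), Cemip (at least 14.8-fold), Olfr397 (at least 10.9-fold), Trim54 (at least 9.09-fold) and Gm9733 (at least 8.07-fold), with adjusted p from 0.0124 for Igsf5 to 0.0403 for Gm9733. In WT, Spag17 and Hrnr were well above background on 1 array, Igsf5 on 2 and Mlip on 3. These 9 were low in sh8 at day -2 and high from day 0 on, and the second probes of Spag17, Olfr397, Cemip and Igsf5 differed by 0.26, 0.73, 0.66 and 0.71. That of Jakmip2 differed by 2.84.

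**Figure D2:**
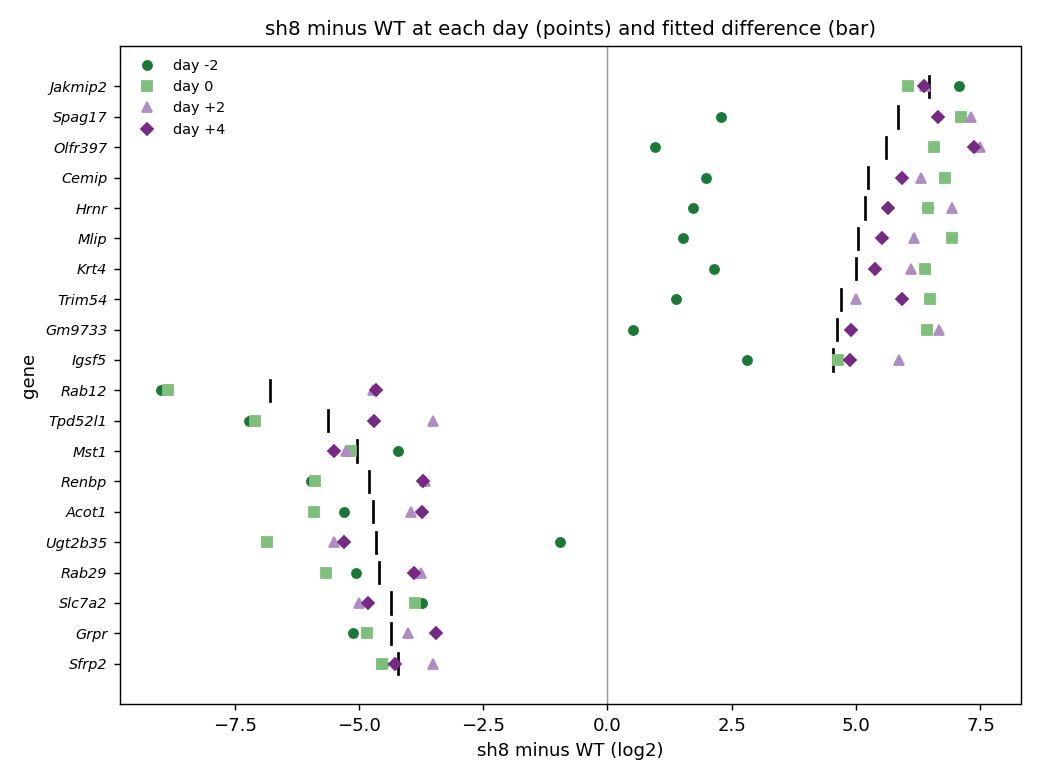
Difference between sh8 and WT in log2 units for the 10 genes highest and the 10 genes lowest in sh8 by fitted difference, with 1 point per day and a black bar at the fitted difference. Jakmip2 was apart by 6.04 to 7.07 on every day, while the other 9 genes higher in sh8 were apart by 0.51 to 2.80 at day -2 and by 4.63 to 7.48 later. Values against a WT or sh8 level below background are no bounds.

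The second question was how expression changed as both lines reached confluence, from day -2 to day 0, on the first slide. Cell division and cholesterol synthesis genes were lower as lists at day 0 by camera with its preset correlation, and none of these 3 lists passed with an estimated one (adjusted p = 0.515 for cholesterol synthesis and 0.559 for S phase and for G2 and mitosis). By limma 0 genes passed over all genes (lowest adjusted p = 0.0543), while 6726 had an unadjusted p under 0.05. Over the list alone 33 of 33 G2 and mitosis genes fell, with a median of -3.26 (camera adjusted p = 4.13e-21), and 31 of 36 S phase genes fell, with a median of -1.83 (5.79e-17). The spindle midzone proteins Prc1 (-3.46 ± 0.53) and Racgap1 (-2.27 ± 0.35) and, in S phase, Pcna (-1.18 ± 0.22) and Cdc6 (-3.03 ± 0.61) had the lowest p in their lists. Cholesterol synthesis genes fell in 21 of 22 cases over the list alone, with a mean of -1.60 (adjusted p = 3.00e-18, fry adjusted p = 0.0326), for example Hsd17b7 (-1.35) and Lss (2.84-fold lower).

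Heat shock and immediate early genes had a median of -1.38, with 10 of 19 lower over the list alone (adjusted p = 2.45e-07, an adjusted p = 0.515 with an estimated correlation). Fos (-4.85 ± 0.33) and the mRNA decay factor Zfp36 (-1.70) had the lowest p, and with normexp the list median was -0.74 (adjusted p = 1.66e-08). Fatty acid synthesis genes had a median of -0.48, with 6 of 15 lower and 1 higher over the list alone (adjusted p = 0.00135, an adjusted p = 0.559 with an estimated correlation), with Acly 1.99-fold lower and Acacb at 1.29. Interferon genes had a median of 0.85 (adjusted p = 2.03e-05, an adjusted p = 0.613 with an estimated correlation), with 2 of 34 higher over the list alone, Ifit2 (0.84) and Tap1 (0.87). Matrix genes had a median of 0.46 (adjusted p = 0.0204, an adjusted p = 0.515 with an estimated correlation, fry adjusted p = 0.00257). In this list 14 of 31 rose and 4 fell over the list alone, among them Mmp2 (2.03) and the collagen chain Col6a2 (2.15-fold higher). Ribosomal protein genes had a median of 0.21 (adjusted p = 0.0312, an adjusted p = 0.559 with an estimated correlation), with 0 of 28 past limma's threshold and 6 at an unadjusted p under 0.05, with the lowest p for Rps24 (0.64) and Rpl7 (0.46, and 0.24 to 0.25 for its other probes). The ribosomal call was lost with quantile scaling (0.889), with normexp (0.366), without day +2 (0.0528), without the filter (0.0621), without day +4 (0.0515) and on the first slide alone (0.0736). The matrix call was lost with normexp (0.283) and on the first slide alone (0.0736), and with quantile scaling the median was 0.30.

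None of the single genes closest to the threshold passed it, and all had an adjusted p of 0.0543. They were Entpd2 (2.67), the phagocytic receptor Mertk (3.31, well above background on 1 array of day -2), Adamts15 (2.57), Wfdc21 (1.87) and Cd300c2 (at least 1.70-fold) on the higher side. On the lower side were Fos, Ralgps2 (-1.77, well above background on 1 array of day 0), Ripk4 (at least 4.74-fold), Gm6602 (at least 3.30-fold) and Epop (at least 2.75-fold). Dnmt1 was at -1.60 (adjusted p = 0.0949) and Fabp4 at -0.51 (0.188), and Pparg (-0.13), Cebpa (-0.086), Cebpb (0.21), Cebpd (0.19) and Cdkn1a (0.35) did not pass. Adipoq was well above background on 0 arrays of either day.

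The next question was what induction changed. At day +2 against day 0, several glucocorticoid and cAMP targets rose and most interferon genes fell, and Fabp4 rose 2.35-fold (log2 change 1.23 ± 0.19, adjusted p = 0.0261). Of 21 glucocorticoid and cAMP targets 8 rose (8 over the list alone), among them the phosphodiesterase Pde4b (11.3-fold up) and, on the log2 scale, Fkbp5 (2.71), Nr4a1 (2.29) and Tsc22d3 (1.68). The list passed at an adjusted p = 0.0107, with an adjusted p = 0.578 with an estimated correlation. Of 34 interferon genes 25 fell (30 over the list alone), with a median of -1.92 (adjusted p = 2.72e-19, an adjusted p = 0.457 with an estimated correlation), among them Ifit2 (-1.94), Irgm1 (-2.43), Gbp3 (-2.78) and Ifit3 (-4.37). Adipoq (at least 1.78-fold, adjusted p = 0.138), Pparg (0.79, 0.0968), Cebpa (0.48, 0.206), Cebpb (-0.049), Cebpd (0.21), Cdkn1a (-0.22) and Dnmt1 (0.73) did not pass. The dimmer second probe of Cdkn1a, well above background on all 8 arrays, was at -1.57.

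Mature fat cell markers rose in 6 of 22 cases (7 up and 2 down over the list alone), such as Rbp4 (well above background on no array of day 0, adjusted p = 0.00879), Car3 (at least 1.58-fold, adjusted p = 0.0279) and the glucose transporter Slc2a4 (at least 1.23-fold, adjusted p = 0.0235). The list passed (adjusted p = 0.0279, an adjusted p = 0.578 with an estimated correlation), but not with normexp (0.0589) or without the filter (0.107). Genes of G2 and mitosis had a median of 2.35 (adjusted p = 5.79e-07, an adjusted p = 0.578 with an estimated correlation). Of these 33, Prc1 (2.61) and Cdc25c (at least 2.24-fold, adjusted p = 0.0367) rose over all genes and 28 rose over the list alone. S phase genes had a median of 1.16 (adjusted p = 2.38e-04, an adjusted p = 0.693 with an estimated correlation). By limma 0 of 36 passed, 15 were higher at an unadjusted p under 0.05, and Pcna (0.96) and Tyms (0.71) came closest. In cholesterol synthesis 1 of 22 genes rose, Hsd17b7 (1.87), also over the list alone, with a list median of 0.58 (adjusted p = 0.00251, an adjusted p = 0.578 with an estimated correlation). Matrix genes fell in 7 of 31 cases (9 over the list alone; adjusted p = 1.07e-04, an adjusted p = 0.373 with an estimated correlation), with smooth muscle actin Acta2 at -3.10, the collagenase Mmp13 at -3.77, Mmp3 at -1.44 and Thbs1 at -1.84. Imprinted genes fell in 5 of 22 cases (7 down and 3 up over the list alone; adjusted p = 0.00298, an adjusted p = 0.373 with an estimated correlation), with Meg3 at -2.87, Slc22a18 at -1.52, Slc38a4 at -1.09 and the preadipocyte factor Dlk1 at -0.92.

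Transcripts of lung and blood appeared on all 4 arrays of days +2 and +4, in both lines, beside each of these groups. The median of 22 measured lung epithelium genes rose from between -6.14 and -5.76 on the first slide to between -2.84 and -2.10 on the second. The surfactant proteins Sftpc (at least 117-fold, adjusted p = 0.00128) and Sftpb (6.87, and 3.74 for its dim second probe), the haemoglobin chains Hbb-b2 (at least 38.3-fold) and Hbb-bt (at least 27.2-fold), and Retnla (7.16) and S100a9 (at least 16.6-fold) of myeloid cells were among the 10 genes that rose most at day +2 by fitted change. Sftpb and Retnla were well above background on 1 array of day 0. Ramp2 (at least 17.7-fold), Eya2 (at least 12.5-fold), Clic5 (at least 11.5-fold) and Spink6 (at least 11.4-fold) were the others, with adjusted p up to 0.0105. Epithelial markers rose in 7 of 13 cases (9 up and 1 down over the list alone; adjusted p = 0.00213, an adjusted p = 0.373 with an estimated correlation), with Krt18 at 2.87, Krt5 at 0.99, and the junction proteins Cldn3 (at least 9.67-fold) and Cdh1 (at least 4.82-fold). Endothelial markers rose in 6 of 11 cases (7 over the list alone; adjusted p = 0.00298, an adjusted p = 0.457 with an estimated correlation), with Esam at 3.43 and Egfl7 at 1.53, and Robo4 at least 11.1-fold and Cldn5 at least 8.77-fold. Lowest by fitted change were Ifit3b (-4.52), Ifit3, Itgbl1 (-4.15), Mmp13, Ifit1 (-3.53), Mamdc2 (-3.53), and Resp18 (at least 8.08-fold), Ttr (at least 6.43-fold), Vmn1r-ps79 (at least 4.51-fold) and Olfr1188 (at least 3.67-fold), with adjusted p between 0.00681 and 0.0364.

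In total 3147 genes changed at day +2, 2378 up and 769 down. Quantile scaling gave 1960 (1210 up and 750 down), the authors' values 1963 (1204 and 759) and normexp 2572 (1510 and 1062), and of 8649 bright genes 962 changed, 423 up and 539 down. Leaving out single arrays mattered: without the sh8 array of day +2 limma called 0 genes (6709 unadjusted), without the WT array of day 0 it called 20, without sh8 day 0 36, without WT day +2 94, and without WT or sh8 day +4 1037 each. Day and slide cannot be told apart in this comparison.

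**Figure D3:**
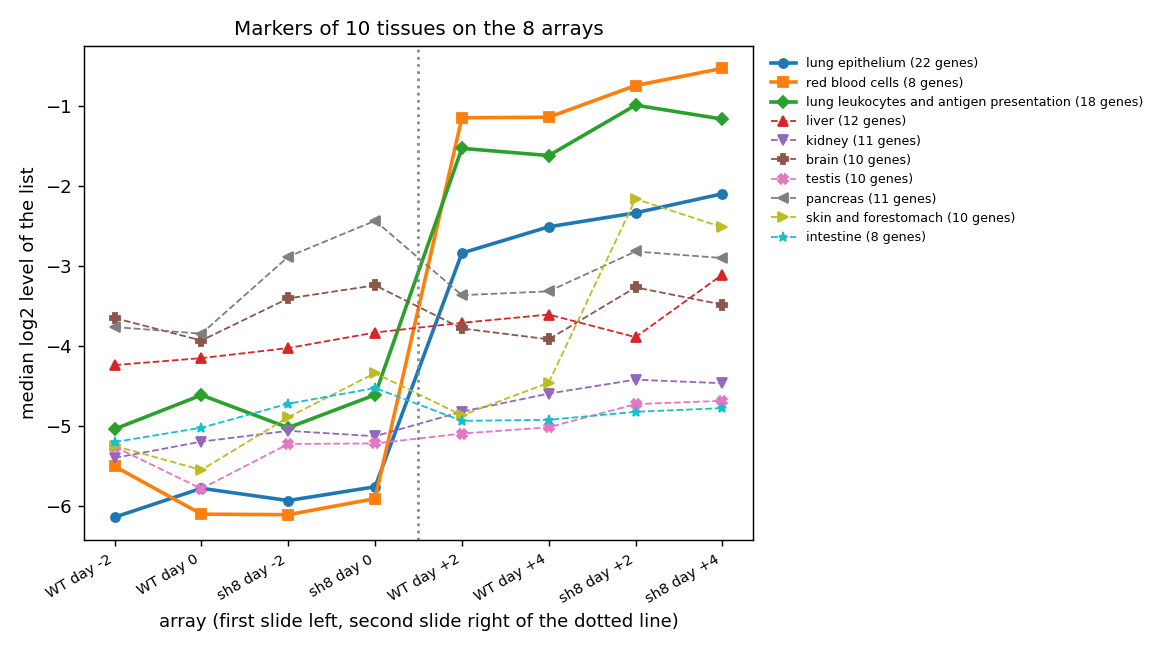
Median normalised log2 level of 10 lists of tissue markers on each array, 1 point per array, with the first slide left and the second slide right of the dotted line. Lung epithelium, red blood cell and lung leukocyte lists rose by medians of 3.51, 3.51 and 3.27 from the first slide to the second, and the lists of the 7 other tissues by 0.07 to 0.88.

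At day +4 against day 0 several fat cell genes rose. Fabp4 rose 4.33-fold (2.11 ± 0.19, adjusted p = 0.00781), Adipoq, the fat cell hormone, at least 4.90-fold (adjusted p = 0.042), and Cebpa, a transcription factor of terminal differentiation, 1.94-fold (0.96 ± 0.22, adjusted p = 0.0429), while Pparg was at 0.85 (adjusted p = 0.068). Cebpb (0.046), Cebpd (0.34), Cdkn1a (-0.21) and Dnmt1 (0.17) did not pass, and the second probe of Cdkn1a was at -1.79. Of 22 mature fat cell markers 10 rose (15 over the list alone; adjusted p = 0.00466, an adjusted p = 0.558 with an estimated correlation), among them Aqp7 (1.57), Rbp4 (at least 1.27-fold, adjusted p = 0.00575) and Car3 (at least 1.80-fold, adjusted p = 0.0154). Interferon genes fell in 29 of 34 cases (29 down and 1 up over the list alone), with a median of -2.31 (adjusted p = 1.95e-22, an adjusted p = 0.463 with an estimated correlation), such as Ifit2 (-2.10), Irgm1 (-2.99), Gbp3 (-3.73) and Oasl2 (-3.76). Glucocorticoid and cAMP targets rose in 8 of 21 cases (10 over the list alone; adjusted p = 0.0156, an adjusted p = 0.706 with an estimated correlation), with Pde4b (3.37), Fkbp5 (2.87), Tsc22d3 (2.37) and Nr4a1 (2.22).

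Imprinted genes fell in 5 cases of 22 and rose in 1 (7 and 1 over the list alone; adjusted p = 7.42e-04, an adjusted p = 0.290 with an estimated correlation), with Meg3 (-2.89), Slc38a4 (-1.36) and Dlk1 (-1.20) lower and Cdkn1c at least 2.57-fold higher (adjusted p = 0.04). Of 31 matrix genes 3 fell and 1 rose, also over the list alone (adjusted p = 0.00455, an adjusted p = 0.290 with an estimated correlation), with Acta2 (-3.26), Thbs1 (-1.71) and Col1a2 (-0.66) lower and elastin Eln (0.95) higher. Epithelial markers rose in 9 of 13 cases (10 over the list alone; adjusted p = 7.42e-04, an adjusted p = 0.290 with an estimated correlation), with Krt18 at 3.41, Krt5 at 1.03, Cldn3 at least 12.7-fold and Cdh1 at least 6.38-fold. Endothelial markers rose in 7 of 11 cases, also over the list alone (adjusted p = 0.00541, an adjusted p = 0.463 with an estimated correlation), with Esam at 3.87, Egfl7 at 2.18, Robo4 at least 14.5-fold and Cldn5 at least 10.7-fold. Each of these groups again stood beside the lung and blood transcripts, with Sftpc at least 137-fold up (adjusted p = 9.89e-04), Retnla 7.70, Sftpb 7.22, Hbb-b2 at least 36.0-fold and Hbb-bt at least 29.9-fold. Igfbp5 (at least 66.4-fold by the mean of both lines), Ramp2 (at least 24.3-fold), Cxcl13 (well above background on no array of day 0, adjusted p = 0.00534), Cstdc4 (at least 18.2-fold) and Clic5 (at least 16.7-fold) completed the 10 highest genes by fitted change, with adjusted p up to 0.0359. Igfbp5 was far apart between the lines, with log2 changes of 3.93 in WT and 8.44 in sh8 against dim values of day 0. Lowest were Ifit3b (-4.87), Ifit3 (-4.37), Ifit1 (-4.15), Gvin1 (-4.11, and -2.31 for its second probe), Oas2 (-4.05), Ifi44 (-3.93) and Resp18 (-3.81, well above background on 1 array of day +4), and Ttr (at least 6.57-fold), 4930539N22Rik (at least 5.64-fold) and Olfr1188 (at least 3.75-fold), with adjusted p between 0.00587 and 0.0486.

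In total 4958 genes changed at day +4, 3814 up and 1144 down, with a median of all genes of 0.19. Quantile scaling gave 3281 (1976 and 1305) and the authors' values 3297 (1961 and 1336), and among the bright genes 1607 changed, 909 up and 698 down. Without the WT or the sh8 array of day +4 limma called 2 genes each (6218 and 6798 unadjusted), without sh8 day 0 it called 74 and without WT day 0 384.

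From day +2 to day +4, both on the second slide, cell division genes were lower and fat cell markers higher as lists by camera with its preset correlation. With an estimated correlation none of the 7 lists that camera called passed (adjusted p from 0.517 to 0.641), and fry called 0 of 29 lists (adjusted p = 0.394 for G2 and mitosis and for fat cell markers). Over the same step the median of the lung epithelium list went from -2.84 to -2.51 in WT and from -2.33 to -2.10 in sh8. By limma 0 genes passed (lowest adjusted p = 0.0883, 1441 unadjusted). Genes of G2 and mitosis had a median of -1.29 (adjusted p = 2.84e-21), with 6 of 33 lower at an unadjusted p under 0.05, among them Hmmr (-0.58) and the proliferation marker Mki67 (-2.44). The median level of the list went from 0.66 to 0.086 in WT and from -0.22 to -2.11 in sh8. Medians were -0.54 for S phase (1.19e-08), with Pola1 at -0.87, -0.46 for interferon genes (1.65e-11), with Ddx58 at -0.61 and Oasl2 at -1.06, and -0.37 for cholesterol synthesis (7.45e-10), with Fdft1 at -0.53 and Nsdhl at -0.60 (-0.90 for its second probe). Fat cell markers had a median of 0.35 (0.0073), with Agt 2.01-fold up, past the threshold over the list alone, and Fabp4 at 0.88. The median level of the fat cell list went from -3.78 to -2.57 in WT and from -3.61 to -3.64 in sh8, and whether the lines differed over this step was not tested. Ribosomal proteins had 0.20 (0.0012), with Rps16 at 0.26 and Rps24 at 0.27, and epithelial markers 0.40 (0.0214), with Esrp1 at 0.58 and Krt19 at 1.40. Quantile scaling ended the ribosomal call (0.653), and with normexp the epithelial median was 0.22. The single genes with the lowest p, none of which passed, were Kcnn2 (1.24), Agt, Vmn2r104 (at least 2.24-fold), Gjd2 (at least 1.31-fold) and Tspyl5 (at least 1.20-fold) on the higher side. On the lower side they were Apold1 (-1.33), Vmn1r227 (-1.34), 2810433D01Rik (at least 2.47-fold), AY512931 (at least 2.01-fold, adjusted p = 0.0906) and Igfals (at least 1.73-fold). Of the 8 genes chosen in advance none passed, with Adipoq at 1.46 (3.01 in WT and -0.083 in sh8), Dnmt1 at -0.57, Cebpa at 0.48, Cebpd at 0.13, Cebpb at 0.095, Pparg at 0.061 and Cdkn1a at 0.0096.

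Whether the difference between sh8 and WT was another one after induction than before was tested directly. The lists of S phase and of G2 and mitosis genes were lower in sh8 relative to WT after induction than before it by camera with its preset correlation. With an estimated correlation each had an adjusted p = 0.760, and fry gave 0.330 and 0.431. The change in the difference had a median of -1.41 for S phase (camera adjusted p = 2.98e-15), with 29 of 36 lower over the list alone, and of -1.66 for G2 and mitosis (6.04e-09), with 0 of 33 past limma's threshold and 17 lower at an unadjusted p under 0.05. Without day +4 the median for G2 and mitosis was -0.89. Inflammatory and acute phase genes had a median of 0.41 (adjusted p = 0.0128), with 0 of 28 passing and 7 higher unadjusted. The lung leukocyte list moved the same way. It was at -0.99 and -1.16 in sh8 and at -1.53 and -1.62 in WT at days +2 and +4. At days -2 and 0 it was at -5.02 and -4.61 in sh8 and at -5.04 and -4.61 in WT. The inflammatory list had an adjusted p = 0.804 with an estimated correlation and 0.431 by fry. Its call was lost without day -2 (median 0.057, adjusted p = 0.4) and without day +4 (0.30, adjusted p = 0.0806), and without day 0 its median was 0.68. The replication factors Gins2 (-1.45 ± 0.17) and Rfc4 (-1.02 ± 0.15, and -1.65 for its second probe), the mitotic genes Racgap1 (adjusted p = 0.151) and Nuf2 (-2.04 ± 0.46), and Nos2 (1.30 ± 0.19) and C3 (0.73 ± 0.16) had the lowest p in their lists, and none passed over all genes.

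**Figure D4:**
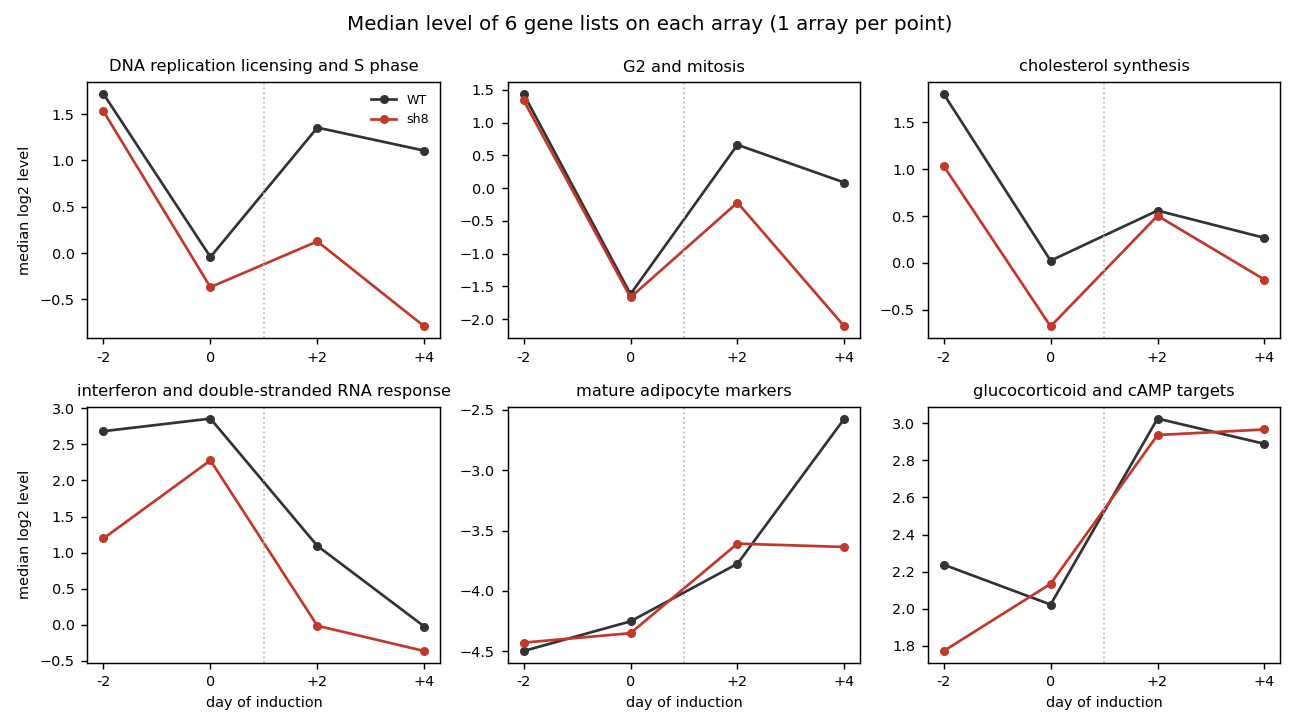
Median normalised log2 level of 6 gene lists by day, WT in black and sh8 in red, 1 array per point and the dotted line between the slides. At day +4 sh8 lay below WT by a median of -2.10 for S phase and -2.46 for G2 and mitosis genes, against -0.13 and 0.029 at day -2.

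For single genes limma called 0 changes of the difference (lowest adjusted p = 0.0947, 5259 unadjusted), where normexp called 1294, the filter on all 8 arrays 1115 and a trended eBayes 1164. The genes with the lowest p, none of which passed, included Rab12, whose difference was -8.98 and -8.83 before and -4.71 and -4.66 after induction, and Nsg1, at -4.10 and -4.25 before and -0.065 and -0.56 after, each well above background on 2 sh8 arrays and all 4 WT arrays. In sh8 Rab12 was not well above background at days -2 and 0, so its differences there have no exact size. Tnfsf11 and Calca were well above background on 2 of the 4 sh8 arrays and on 0 of the WT arrays, and the receptor gene Olfr1328, with 1 and 2 such arrays, also had a higher difference. On the lower side were the leukocyte genes Wdfy4 (a change of -3.99) and Fli1 (-2.44), both well above background on 2 WT arrays. Olfr1413 (-3.58), Fam181b (-3.01) and Olfr295 were also lower. Fam181b was well above background on 1 sh8 and 2 WT arrays, and Olfr295 on 2 WT arrays and 0 sh8 arrays. The difference of Wdfy4 narrowed from 5.58 and 5.90 to 1.94 and 1.55, and that of Fli1 from 4.95 and 4.97 to 2.56 and 2.47. Those of Rab12 and Nsg1 narrowed too, while those of Tnfsf11 and Calca widened and the others changed sign. The arrays after induction are those with the lung and leukocyte transcripts, which cannot be told apart from induction here. Pparg (-0.62, adjusted p = 0.2), Adipoq (-1.45, 0.521), Dnmt1 (-1.04, 0.15), Fabp4 (0.38), Cebpa (0.31), Cebpb (-0.059), Cebpd (0.38) and Cdkn1a (-0.27) did not pass.

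On single days sh8 and WT were compared array against array, with no test. At day -2, 2336 of 22694 genes differed at least 2-fold, 1258 higher and 1078 lower in sh8. Quantile scaling and the authors' values each gave 931 higher and 1143 lower, and normexp 431 and 433. The largest differences were Acot1 (-5.30), Grpr (-5.12), Rab29 (-5.07), Sfrp2 (-4.52) and Fbln7 (-4.51), and Ecscr (3.47), Mctp1 (3.46), Lrrc75b (3.45), Pcolce2 (3.44) and Lilrb4a (3.27). At day 0, 2614 of 22178 differed, 1527 higher and 1087 lower. Quantile scaling gave 1202 higher and 1209 lower, the authors' values 1206 and 1209 and normexp 557 and 404. Lowest in sh8 were the matrix protein Sparcl1 (-5.34), Mst1 (-5.15), Lrrc17 (-4.89), Grpr (-4.83) and Sfrp2 (-4.54). Highest were Prss50 (5.25), Gzmc (4.89), 1700066M21Rik (4.86), Cd55 (4.65) and Igsf5 (4.63). At day +2, 5106 of 26063 differed, 3671 higher and 1435 lower. Quantile scaling gave 2578 and 2011, the authors' values 2486 and 2008 and normexp 1065 and 824. The genes were Ugt2b35 (-5.49), Mst1 (-5.26), Slc7a2 (-5.00), Rab12 (-4.71) and Ppef1 (-4.57), and Mlip (6.16), Prss50 (5.93), Gzmc (5.77), Igfbp5 (5.64) and Tlx1 (5.53). At day +4, 3860 of 26124 differed, 2494 higher and 1366 lower, where quantile scaling gave 2073 and 1876, the authors' values 2012 and 1827 and normexp 898 and 794. Mst1 (-5.50), Ugt2b35 (-5.30), Slc7a2 (-4.82), Gm13582 (-4.79) and Rab12 (-4.66) were lowest, and Spag17 (6.65), Hrnr (5.64), Mlip (5.53), Arl14epl (5.19) and Prss50 (5.12) highest.

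By list, the S phase median lay at -0.13, -0.55, -1.24 and -2.10 at days -2, 0, +2 and +4, at percentiles 3.80, 0, 0 and 0 of matched random lists. That of G2 and mitosis lay at 0.029, -0.17 and -2.46 at days -2, 0 and +4 (percentiles 33.1, 2.42 and 0), with percentile 0 also at day +2. Mature fat cell markers were at -0.037, -0.070 and -0.16 up to day +2 (12.9, 11.5 and 1.29) and at -0.78 at day +4 (0). Interferon genes were at -1.21, -0.42, -0.87 and -0.19 (0, 0.01, 0 and 8.62). The inflammatory list was at -0.27, 0.15, 0.55 and 0.41 at days -2, 0, +2 and +4 (0.14, 97.13, 99.99 and 99.95). Days +2 and +4 are those with the lung transcripts. The random lists were not matched on the correlation between genes, so these percentiles give a place and no p-value.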

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

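The tests of array position and that of normalisation for the S phase list were chosen after the result was seen; the tests of unequal lung RNA and of normalisation for the G2 and mitosis list were not, nor was that of other splits of the days. In 3 lists the difference between sh8 and WT changed after induction by the test of the change itself, with camera's preset correlation. The median change was -1.41 for S phase, -1.66 for G2 and mitosis and 0.41 for inflammatory and acute phase genes (camera adjusted p = 2.98e-15, 6.04e-09 and 0.0128). With an estimated correlation the adjusted p was 0.760, 0.760 and 0.804. Without day +4 the G2 and mitosis median was -0.89, and the inflammatory one was 0.68 without day 0, 0.057 without day -2 (adjusted p = 0.4) and 0.30 without day +4 (0.0806). The inflammatory list is given as a value only.

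Cell cycle genes were lower in sh8 than in WT after induction, with medians of -1.24 and -2.10 at days +2 and +4 for S phase and of -2.46 at day +4 for G2 and mitosis, and with 32 of 33 genes lower at day +4 in each of the 5 scalings tried. Unequal lung RNA between the lines would lower all genes of the cells. The 8693 genes bright on the first slide differed at day +4 by a median of -0.082 (quartiles -0.42 and 0.24). Each array was scaled to its own percentile, which largely removes a lowering shared by all genes, so this median does not decide it. The lung epithelium median at day +4 was -2.10 in sh8 and -2.51 in WT. Scaling keeps gaps between genes, and both cell cycle medians at day +4 lay below that lower quartile. A lowering shared equally by all genes of the cells would not give this gap. Array position would act on both slides, but at days -2 and 0, with sh8 at the same positions, the G2 and mitosis median farther from 0 was -0.17, which argues against it for that list on 2 pairs of arrays; the S phase median was already -0.55 at day 0, so position stays open for part of that difference. Under the other 4 scalings the medians at day +4 nearest to 0 were -1.83 and, for S phase, -1.82 (both normexp). These values argue against the choice among these scalings as the cause. Quantile scaling and the authors' values nearly coincided (-2.18 each for S phase), so they are not separate checks. A difference between the lines themselves stays open and untested, since each line and day has 1 array and no line with a control shRNA was among the samples, and a culture that divided later or less may give the same values; 2 G2 genes looked at after their values were seen, Mki67 (2.29) and Cenpe (1.33), were higher in sh8 at day +2, when the median of that list was lower in sh8, between -1.02 (median scaling) and -0.88 (normexp) under the other 4 scalings.

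Among splits of the 4 days into 2 and 2, all 3 gave as many genes as the real one, which was 0 (highest other 0), and 3 splits are too few for a share under 0.05. The unadjusted counts were 5259 for the real split and 652 and 451 for the others.

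Outside the gene probes, 2 of 22 spike-in probes were well above background on all 8 arrays and 11 on none. One is an ERCC probe with levels from -0.98 to 0.75 and a mean of -0.075, the other an E1A probe with a mean of -5.00, the highest of the 10 E1A probes. No explanation was tested.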

How the results depend on the processing

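The first-slide, second-slide and bright-gene alternatives, and those of day +4 against day +2, were chosen after the data were seen. Of the alternative counts, 102 stayed within 1.5 times the main one, 36 fell below and 10 rose above it. Of list medians 248 kept their call, 81 lost it and 0 passed in the other direction. Of tested gene values 8354 kept their side of the threshold and their sign, and 1739 lost the call with the same sign. Another 315 gained a call, and their sign was not compared. A further 52 turned sign where neither setting passed, and 3 turned sign where the main setting passed. For sh8 against WT (7158), leaving out the block of paired days gave 1408, the first slide alone 0 (8387 unadjusted), and leaving out a day from 0 (day +2 or +4) to 4212 (day -2). The smaller counts without a day come with fewer arrays, and a lone array left at a day is assumed to vary like the others. The shared days pair the arrays of the lines, and without this block the change after induction also gave 0. For day 0 against day -2 (0 by limma, 6726 unadjusted), normexp gave 3484, the authors' values 10, the filter on all 8 arrays 1672 and the trended eBayes 1944. For day +2 against day 0 (3147) quantile scaling gave 1960, the authors' values 1963, no line term 668, bright genes 962 (fewer genes tested), and leaving out an array 0 to 2504. For day +4 against day 0 (4958) the values were 3281, 3297, 1271, 1607, and 2 to 4098. For day +4 against day +2 (0 by limma, 1441 unadjusted) quantile scaling, the authors' values and no line term gave 1 gene each. For the change after induction (0, 5259 unadjusted) normexp gave 1294, the filter on all 8 arrays 1115 and the trended eBayes 1164. The counts at least 2-fold apart at days -2, 0, +2 and +4 (2336, 2614, 5106 and 3860) became 864, 961, 1889 and 1692 with normexp, 1100, 1283, 2195 and 1678 with a log2 difference of 1.5, and 1402 and 1547 at days -2 and 0 with both arrays above background. Of the 7 lists called for sh8 against WT, 0 passed with an estimated correlation and 4 by fry, 2 of them among the 7. Of the genes that passed in the main setting, those turned in sign were Prdm16 for sh8 against WT, with quantile scaling (-0.0050) and in the authors' values (-0.065, in place of 0.35), and Zfp467 at day +2, with the mean over its probes (0.33 in place of -0.67). Apart from fewer arrays or genes, the cause was not tested. Scaling moved the median of all genes: the sh8 minus WT median at day +4 was 0.16 in the main setting and 0.03 with quantile scaling. Slide could not be added as a block to the comparisons of day +2 or +4 with day 0, nor to the change after induction. Signal over background limits the dim genes, whose changes are given as bounds.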

Other observations

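The tests of lung RNA, of dim probes and of induction by the medium, those of single probes and of a change of the culture, and the tissue lists were chosen after the results were seen; the test of another tissue in sh8 and that of other splits of the arrays were not. Some groups that moved in both directions between sh8 and WT were not described above. Of 28 CDK inhibitor and p53 target genes 5 rose and 4 fell (5 and 5 over the list alone), with the cyclin Ccnd1 (0.72) and Btg2 (0.89) higher and the inhibitors Cdkn1b (-0.63) and Cdkn2c (-1.25) lower. Of 24 genes of DNA methylation 4 rose and 5 fell (5 and 6 over the list alone), with a median of 0.012, a mean of -0.089 and a camera direction of down, among them Cxxc5 (0.83), Cxxc4 (0.70, but -0.46 for its second probe), and the histone methyltransferases Ehmt2 (-0.53) and Ezh2 (-1.04). Imprinted genes rose in 6 and fell in 5 of 22 cases (7 and 5 over the list alone), with Slc22a18 at 1.98, Peg3 at 1.12, Nnat at 0.81 and Snrpn at -1.09. Of 25 unfolded protein and stress response genes 6 rose and 1 fell (7 and 2 over the list alone), with the cystine transporter Slc7a11 at 1.97, Nupr1 at 0.65, Creld2 at 0.65 and Dnajc3 at 0.56. Of 28 inflammatory genes 2 rose and 2 fell, also over the list alone, with Il6 at -1.66 and the chemokine Cxcl12 at -1.20 but Ptgs2 at 1.36 and Ccl2 at 0.59. Of 16 genes of triglyceride synthesis 5 rose and 2 fell, also over the list alone, with Pnpla3 (1.35) and Mgll (0.78) higher and Plin3 (-0.94) and Gpam (-0.73) lower. None of these 6 lists passed camera (adjusted p from 0.409 to 0.9).

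Lung and blood transcripts appeared on all 4 arrays of the second slide. Of 24 lung epithelium genes 22 were measured, with a median rise of 3.51 from the first slide to the second and 14 genes up by more than 2. On the second slide Lamp3 was at 3.24 (3.00 on the first), Cyp2f2 at 2.83 (0.33) and Scgb1a1 at 1.27 (-3.44), each by its own probe. Sftpc was at 1.44 and well above background on 0 arrays of the first slide, and Sftpb was at 0.77 and well above background on 1 of them. The 20 genes of the list that are named in no comparison had a median of 2.91, with 16 up by more than 1, while Lamp3 (0.24), Muc1 (0.64), Aqp5 (0.68) and Cldn18 (0.94) moved little. Red blood cell genes (8 measured) rose by a median of 3.51 and lung leukocyte genes (18, 4 of them also in a list fixed in advance) by 3.27, although Cd74 changed by -0.42. The 7 lists of other tissues rose by 0.42 (liver, 12 genes), 0.52 (kidney, 11), 0.28 (brain, 10), 0.60 (testis, 10), 0.068 (pancreas, 11), 0.88 (skin and forestomach, 10, of which 2 are in a fixed list) and 0.20 (intestine, 8). In skin and forestomach the sh8 arrays of days +2 and +4 stood apart at -2.16 and -2.51, against -4.87 and -4.46 in WT. Sprr1b, Krt4 and Ivl made most of this gap, at -2.07, -0.77 and -2.22 in sh8 at day +2, against -5.95, -6.88 and -6.06 in WT. Krt5 (-2.10 against -2.39), Krt14 (-3.51 against -3.69) and Krt10 (-0.93 against -0.94) differed little. Krt13 was lower in sh8 (-4.15 against -3.94).

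A rise of all dim probes on the second slide was set against the 7 lists of other tissues, whose highest median rise was 0.88. Many of their genes were not dim, being well above background on every first-slide array, so these medians do not decide it. Of their genes above background on 0 first-slide arrays, Sprr1b (3.82), Mup20 (2.51), Stmn2 (2.39) and Umod (2.01) rose most. Slc12a1 (0.52), Lct (0.057) and Vil1 (-0.12) rose least or not, and the others by 0.60 (Apoa4) to 1.71 (Alpi). Such genes were kept only if well above background on at least 2 second-slide arrays. The filter thus favoured a rise, and these values do not decide it either. A rise of dim probes therefore stays open for part of the values. RNA from lung tissue in the 4 samples of the second slide is a candidate explanation, since the lung list rose by 2.62 more than the highest of the other 7. It may have entered at any step up to hybridisation, and the lung genes that moved little speak for no exact share. Induction of these genes by the medium cannot be told apart from it, because 0 arrays of day +2 or +4 lay on the first slide.

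A set of genes was high on the sh8 arrays of days 0, +2 and +4 and low on the sh8 array of day -2 and in WT. The set was defined after its values were seen and holds 30 transcripts, 18 of them named, with 3 in the mirror pattern in WT and 0 low instead of high in sh8. RNA from another tissue in the 3 sh8 samples was tested with the 10 tissue lists, without the genes of the set. They rose in sh8 from day -2 to day 0 by a median of at most 0.57 (pancreas), which argues against these tissues for the day 0 sample. Other tissues and days +2 and +4 were not part of this test and stay open. With Krt4, a gene of the set, left in, the skin and forestomach list in sh8 was at -4.89, -4.34, -2.16 and -2.51 at days -2, 0, +2 and +4. Signal of single probes from another transcript is a candidate explanation: for the 6 genes with another probe the chosen probes rose by a median of 5.10 and the others by 0.33, with none above 3, though the others were dim and so weak evidence, and for 54 other genes called at least 4-fold the values were 2.52 and 0.78, with 81.5% in the same direction. A change of the sh8 culture between day -2 and day 0 stays open, since only 1 sh8 array of day -2 exists.

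Other splits of the 8 arrays into 4 and 4 were compared with sh8 against WT. Of 35 splits 3 could not be fitted; of the other 32, 1 gave 7158 genes or more, the real one, and the highest other gave 1 gene. Most of these do not keep the pairing by day. Only 8 splits part both arrays of every day, as the real one does; their highest other gave 0 genes, and 8 are too few for a share under 0.05. The real split also follows the array position on the slides.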
